A study of Homo sapiens with 6 samples.

How the data were processed

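RNA was sequenced from 22Rv1, an established human prostate cancer cell line. Per the labels' protocols, docetaxel-resistant cells (DTXR) were kept in medium with 10% serum and 3 nM docetaxel, a taxane that stabilises microtubules, and docetaxel-sensitive cells (DTXS) were kept alongside with ethanol. DTXR cells were also treated for 72 h with ethanol as vehicle or with 25 µM of a compound that the labels name only as Dic. There were 6 libraries: 1 of DTXS, 1 of DTXR, 2 of DTXR with vehicle and 2 of DTXR with Dic. Total RNA was extracted with a column kit and sequenced as single reads of 50 nt, per the labels' protocols, which do not say whether poly(A) RNA was selected or strand was kept. Demultiplexing used Bcl2fastq2 2.17, per the labels' protocols. Bowtie2 2.4.0, RSEM 1.3.3, edgeR and the hg19 build are named in the submitters' processing notes, without roles or order, and the gene annotation is not given in the sources used here.

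The authors made 2 tables, normalized separately, and every test was run within 1 table. The table of DTXS and DTXR holds counts-per-million (CPM) after TMM normalization, per the labels. The table of the Dic and vehicle libraries holds a normalized signal that the authors also made as TMM-normalized counts-per-million, and since its library sizes were scaled by TMM factors its columns do not share 1 total; these values are called CPM throughout. The design fixed beforehand assumed CPM for both tables, and the test on log2(CPM + 1) was kept for both. The tables listed 25343 and 26475 gene rows, respectively, of which 24751 symbols were shared. There were 28 symbols that read like dates in the DTXS and DTXR table, and these rows were kept but never named. Every value was a whole multiple of what 1 read was worth in its library, within 0.01 of a read for 100% of values, so whole reads were recovered: 16762158 for DTXS, 15692336 for DTXR, 30681499 and 24741216 for the vehicle libraries and 23309675 and 29134852 for the Dic libraries. A count of 0 allowed a level of up to 3 reads, which was 0.168 CPM in DTXS, 0.181 CPM in DTXR and between 0.099 and 0.127 CPM in the other libraries. The TMM factors implied by these reads multiplied to 1 in the Dic table and to 1.13 in the DTXS and DTXR table; the cause of the latter was not tested.

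Dic and vehicle libraries were compared with limma 3.58.1 (lmFit and eBayes with a mean-variance trend, two-sided) in R 4.3.3 on log2(CPM + 1) for genes with a mean of at least 1 CPM, and genes with a Benjamini-Hochberg adjusted p below 0.05 were called. Fold changes are on this log2(CPM + 1) scale, which understates the change of low genes. With 2 libraries against 2, an exact permutation test of a single gene could not give a p below 0.333. The labels do not say that the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The replicates differed by more than sampling noise (mean chi-square per gene of 5.21 between the Dic libraries and 7.26 between the vehicle libraries, for 1 degree of freedom), so each counted as a library of its own. The 31 gene lists were fixed before the data were examined, and 686 of their 699 members were found in each table, through older symbols where needed; no member of the list of mitochondrially encoded genes was among them. The 26 lists with at least 5 tested members were tested with camera and with fry. Camera used a preset correlation of 0.01 and an estimated correlation, which has 2 residual degrees of freedom here and so little power. The estimates were 0.254 for amino acid stress, 0.452 for S phase, 0.525 for G2 and mitosis and 0.086 for cholesterol synthesis. They were below 0.01 for fatty acid synthesis (-0.075) and immediate early genes (-0.021). Where members of a list move together more than the preset value allows, its p-values at the preset correlation are too small. The fry p-value asks whether a list's genes move, on balance, in 1 direction, without comparing them with other genes.

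DTXS and DTXR had 1 library each, so no p-value was computed. Log2 ratios of (CPM + 1) were taken for genes with a mean of at least 1 CPM, and each list's median was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. Random lists were drawn gene by gene, whereas members of a list can move together, so these placements are descriptions and not tests. Ratios of single genes carry exact 95% intervals from the recovered reads, which cover counting error only. Genes at least 2-fold apart between DTXR and DTXS were then tested as sets in the Dic comparison.

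The genes named were set by a rule written before the data were examined: the 12 largest rises and 12 largest falls among called genes whose Dic libraries both lay beyond both vehicle libraries, the 12 highest and 12 lowest ratios of DTXR to DTXS, up to 4 members of each list with the largest change, and genes named in any case (CHRM1, CHRM3, ABCB1, KLK3, MET, HGF, CHGA, TUBB3, HMGCS1 and MKI67). Some genes that the rule picked are not used here. Symbols with the prefixes of unnamed loci and of some small RNAs (among them RN7S, but not RMRP or RPPH1), and those of ribosomal pseudogenes, antisense genes and readthrough genes, were left out of the rankings. Alternatives set beforehand were pseudocounts of 0.1 and 5 CPM, no filter, a filter at 5 CPM, rescaling each library to a common total, centring on the library median, no variance trend, the replicate number as a block, leaving out each library in turn, which leaves 1 library in its group so that the spread comes from the other group alone, and stricter thresholds. Chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 on the recovered reads, and a fit without rRNA and RNA polymerase III genes. The code was tested on simulated data with 200 genes of the Dic comparison changed. There limma recovered 38% of the 50 genes changed 1.25-fold, 72% at 1.5-fold, 98% at 2-fold and 96% at 4-fold. It called 9 of the 13377 genes left unchanged, with 13513 changed and unchanged genes tested in all. Simulated genes were independent, with a variance set by the trend alone. The simulation thus checks the code and does not give the error rate of the real calls. Gene order along chromosomes was taken from the RefSeq gene table of a later assembly than hg19, for neighbours only. Figures were drawn with matplotlib 3.10.9 in Python.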

Results

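The transcriptomes of 22Rv1 prostate cancer cells were measured by RNA sequencing in 6 libraries, in a study of the muscarinic acetylcholine receptor CHRM1 in resistance to docetaxel. A first table held 1 library of docetaxel-sensitive cells (DTXS) and 1 of docetaxel-resistant cells (DTXR), with 16762158 and 15692336 reads assigned to genes. A second table held DTXR cells after 72 h with ethanol vehicle (2 libraries, 30681499 and 24741216 reads) or with 25 µM Dic (2 libraries, 23309675 and 29134852 reads). All values are TMM-normalized counts-per-million (CPM). The tables were normalized separately, so levels set across them are given only as values.

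The series names CHRM1, so the muscarinic receptors come first, in every library. CHRM1 was at 5.61 CPM in DTXS (100 reads) and 2.47 CPM in DTXR (41 reads). In the other table it was at 2.71 ± 0.852 CPM (SD, n = 2) with vehicle and 3.23 ± 0.738 CPM with Dic, a log2 fold change of 0.20 ± 0.19 (SE) with a limma adjusted p of 0.587. Leaving out vehicle replicate 1 turned this fold change to -0.04. CHRM3, which like CHRM1 couples to Gq, was at 58.5 CPM in DTXS and 41.3 CPM in DTXR, but at 2.20 ± 0.135 CPM with vehicle and 3.35 ± 0.852 CPM with Dic (adjusted p = 0.151). CHRM4, a Gi-coupled receptor, had 13.2 CPM in DTXS and 11.4 CPM in DTXR, and it rose from 19.5 ± 2.38 CPM to 24.8 ± 1.56 CPM under Dic (adjusted p = 0.035). That call was lost without vehicle replicate 2 (adjusted p = 0.314), without Dic replicate 1 (0.0704) and without Dic replicate 2 (0.243). CHRM2 was listed at 0 in DTXS and DTXR at 1.05 and 1.24 CPM with vehicle and at 0.465 and 0.507 CPM with Dic, below the filter, and CHRM5 had no read in DTXS or DTXR and at most 2 reads in any other library.

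The resistant and the sensitive cells were compared to see what separates them without Dic. DTXR cells were kept with docetaxel and DTXS cells with ethanol, so this comparison cannot tell resistance apart from ongoing docetaxel exposure. ABCB1, which encodes the efflux pump P-glycoprotein that exports taxanes, was nearly silent in DTXS (2 reads, 0.112 CPM) and among the abundant transcripts of DTXR (574 CPM, 9533 reads), a ratio of 5115 with a counting interval of 1420 to 42200. UROD, an enzyme of haem synthesis, was 37.8-fold higher in DTXR (34.5 against 1301 CPM). The insulin-like growth factor binding protein gene IGFBPL1 was 88.7-fold higher (11.1 against 980 CPM). On the other side, ASS1, which makes argininosuccinate in arginine synthesis, was at 1236 CPM in DTXS and had 93 reads in DTXR, a ratio of 221 (180 to 273). Each ratio compares these libraries and has no replicate check.

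Of 13684 measured genes, 758 were at least 2-fold higher and 562 at least 2-fold lower in DTXR, and 139 and 135 were at least 4-fold apart in the same directions. With a pseudocount of 0.1 CPM the latter counts were 277 and 262, and with 5 CPM 47 and 49. The highest ratios beyond those above were those of TARP, CGA (the shared alpha subunit of glycoprotein hormones), F3 (tissue factor), GPR85, SLFN11, STMN4, SERF1A, CEACAM6 and TUNAR. CGA had 4 reads in DTXS and 589 in DTXR (158-fold, 61.4 to 582), and SLFN11, a gene tied to the response to DNA damage, had 2.69 and 73.7 CPM. SERF1A had no read in DTXS and 269 in DTXR, at least 96.2-fold higher, but it has a near-identical copy with which it can share reads, so its value is uncertain. The lowest ratios after ASS1 included those of SHF, STC1 (the secreted glycoprotein stanniocalcin), FZD8 (a Wnt receptor), KLF13, PCP4L1, ELF5, TNS1, GPR161, DDX53 and EGR3. STC1 was at 190.5 CPM in DTXS and 1.39 CPM in DTXR, and DDX53, with 274 reads in DTXS and none in DTXR, was at least 85.1-fold lower.

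**Figure D1:**
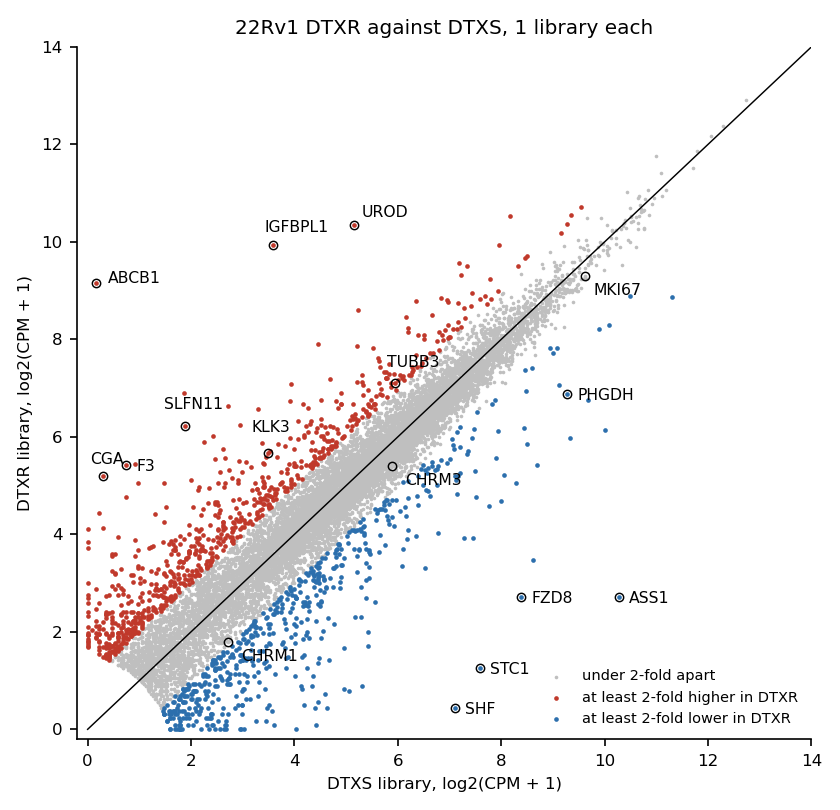
Expression of 13684 genes in the DTXS library (horizontal) and the DTXR library (vertical), both as log2(CPM + 1), 1 library each. The line marks equal values, red and blue points are genes at least 2-fold higher (758) or lower (562) in DTXR, and circled genes are labelled; ABCB1 stands alone at the upper left with 0.112 CPM in DTXS and 574 CPM in DTXR.

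Among the fixed lists, 11 of 27 had a median ratio above the central 95% of matched random lists. Placements among random lists ignore that members of a list can move together, so they describe these libraries and are not tests. The list of drug transporters, which also holds genes of taxane metabolism, had 5 of 10 members at least 2-fold higher in DTXR and none lower. Its median log2 ratio was 0.78, against -0.31 to 0.36 for random lists. Besides ABCB1 these included ABCC2, a conjugate export pump (15.0 against 52.8 CPM), ABCC6, and ABCB4, the paralog next to ABCB1, with 4 and 37 reads. Androgen response genes had 9 of 27 members at least 2-fold higher and 2 lower, with a median of 0.59 above all 10000 random lists. KLK3, which encodes prostate-specific antigen, was at 10.2 CPM in DTXS and 50.2 CPM in DTXR, and PART1 at 4.10 and 30.1 CPM, while ALDH1A3 was lower in DTXR (7.80 against 0.542 CPM).

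Tubulins and microtubule-binding proteins, the structures that docetaxel acts on, were higher in 19 of 21 cases, with a median of 0.21. TUBB3, the class III beta-tubulin, was at 61.0 CPM in DTXS and 136 CPM in DTXR, TUBA1A at 28.8 and 101.7 CPM and MAP1B at 220 and 606 CPM, whereas the tau gene MAPT was lower (122 against 42.9 CPM). Lysosomal genes were higher in 23 of 29 cases (median 0.23), among them GPNMB (25.2 against 52.9 CPM) and the sialidase gene NEU1 (30.2 against 55.5 CPM). Unfolded protein response genes were higher in 16 of 17 cases (median 0.29), with CRELD2 at 129 and 264 CPM. The cholinergic list had a median of 0.62, led by acetylcholinesterase (ACHE, 4.55 against 23.5 CPM), with CHRNA3 and BCHE also higher and CHRM1 lower. Neuroendocrine genes had a median of 0.51, with CHGB at 19.4 and 58.9 CPM and SCG2 at 1.46 and 6.26 CPM. Of 12 members 4 were at least 2-fold higher and 2 lower, the lineage factor genes SOX2 (32 reads in DTXS, 4 in DTXR) and NKX2-1 (44 and 9 reads). CHGA was low (29 reads in DTXS, 12 in DTXR). The other 4 of the 11 lists were hypoxia and glycolysis (0.37; BNIP3L higher, PFKFB3 lower), replication-dependent histones (0.79; HIST2H2BE at 15.1 and 41.6 CPM), mesenchymal genes (0.58; ITGA5 higher, CDH2 lower) and NF-kB targets (0.56; BIRC3 higher). Histone transcripts mostly lack a poly(A) tail, so their level can also move with library preparation.

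Proliferation genes were lower in the DTXR library than in the DTXS library. Of 53 genes of G2 and mitosis 48 were lower, with a median log2 ratio of -0.40, and of 43 S-phase genes 38 were lower, with a median of -0.32; both medians lay below all 10000 random lists. The replicative helicase subunit MCM2 was at 398 CPM in DTXS and 245 CPM in DTXR, PCNA at 173 and 111 CPM, the mitotic kinases AURKA and AURKB at 65.9 and 36.1 CPM and at 54.7 and 29.9 CPM, and MKI67 at 786 and 630 CPM. Respiratory chain subunits were the third list below the random range (median -0.20), with CYC1 at 422 and 276 CPM. The vehicle libraries of DTXR cells lay above the DTXR library for all of these lists. Their median log2 differences were 0.544 (S phase), 0.485 (G2 and mitosis) and 0.416 (respiratory chain). MKI67 went the other way, at 330 and 271 CPM with vehicle. These sets of libraries were normalized separately, so whether the lower levels hold for DTXR cells in general cannot be told. The other 13 lists lay inside the random range, with medians from -0.06 for heat shock genes to 0.32 for basal prostate markers. Within them the amino acid stress list held large differences in both directions: PHGDH, the first enzyme of serine synthesis, was at 618 CPM in DTXS and 117 CPM in DTXR, the amino acid transporter SLC7A5 at 956 and 296 CPM, and PPP1R15A at 15.8 and 34.5 CPM. Of the growth factor receptors, EGFR was at 52.8 and 12.8 CPM, MET at 11.3 and 12.8 CPM, and its ligand HGF at 1.74 and 4.64 CPM. HMGCS1 was at 75.2 and 89.7 CPM. Lists of endothelial, fibroblast and immune markers had fewer than 5 measured members, with highest mean levels of 2.20 CPM (ENG), 10.2 CPM (COL1A1) and 27.2 CPM (HBA1).

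Dic and vehicle were compared in DTXR cells to find what the compound does to resistant cells. Dic raised genes of the amino acid stress response, of cholesterol and fatty acid synthesis and of the lysosome, and lowered S-phase genes, by camera at the preset correlation. With an estimated correlation none of these lists passed (adjusted p = 0.201 for each of the 4 rising lists and 0.404 for S-phase genes), and by fry S-phase genes did not pass either (adjusted p = 0.107). Stearoyl-CoA desaturase (SCD) rose from 443 ± 24.2 to 1006 ± 21.4 CPM (SD, n = 2 each), the stress transcription factor DDIT3 from 41.0 ± 3.38 to 77.8 ± 7.46 CPM and INSIG1, a regulator of sterol synthesis, from 130.4 ± 5.33 to 225 ± 0.784 CPM, while the DNA methylation cofactor UHRF1 fell from 164 ± 0.273 to 120 ± 5.27 CPM. ABCB1 was at 526 ± 2.07 CPM with vehicle and 579 ± 19.4 CPM with Dic, a log2 fold change of 0.14 ± 0.05 (SE) that did not pass (adjusted p = 0.0672). It passed when the libraries were rescaled to a common total (adjusted p = 0.0136), with the replicate block (0.0232) and without vehicle replicate 1 (0.0468).

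Of 13577 genes tested with limma, 1256 changed, 796 up and 460 down, mostly by little: the median absolute log2 fold change of called genes was 0.31, and 39 changed at least 2-fold (23 up, 16 down). Both Dic libraries lay beyond both vehicle libraries for 52.4% of tested genes, against 33.3% by chance. The largest rises with a level above 0 in vehicle were those of GPNMB, a lysosomal membrane glycoprotein (8.58 ± 0.320 to 27.0 ± 0.121 CPM, log2 fold change 1.55 ± 0.10, adjusted p = 1.99e-10), and PDK4, a kinase that inhibits pyruvate dehydrogenase (100.3 ± 2.44 to 291 ± 11.9 CPM, 1.53 ± 0.05, adjusted p = 2.75e-15). They were followed by GEM, LAMP3, the carbonic anhydrase gene CA12 (42.1 to 99.2 CPM), the stress cytokine gene GDF15 (123 to 287 CPM), CREB3L1, FAM129A and TSC22D3, with log2 fold changes between 1.19 and 1.46. CTAGE4 was listed at 0 in both vehicle libraries and at 3.89 and 4.76 CPM with Dic. It belongs, like RBMY1A1 and RBMY1B, which rose, and RBMY1D and RBMY1E, which fell, to families of near-identical copies that can trade reads, so these values are uncertain.

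The largest falls were among ribosomal and small non-coding RNAs. The 18S, 28S and 45S precursor RNAs (RNA18S5, RNA28S5 and RNA45S5) fell by 3.97, 3.12 and 2.22 on the log2 scale, and RMRP and RPPH1 fell by 3.61 and 3.30. The Dic libraries lay far apart for some of these. Dic replicates 1 and 2 had 1317 and 478 CPM of RNA18S5, 1.86 and 0.135 CPM of RMRP and 1.52 and 0.0338 CPM of RPPH1. The size of these falls is therefore uncertain. Together rRNA made up 3.90% and 4.83% of the vehicle libraries and 0.62% and 0.35% of the Dic libraries, so this share differed between the groups for every gene group described here. Without rRNA and RNA polymerase III genes, and with each library rescaled, 1276 genes changed (702 up, 574 down). Among protein-coding genes the largest falls included those of the cancer-testis gene SSX2, GOLGA8R, PTN and the prostate-specific transporter gene SLC45A3 (24.2 to 15.0 CPM, log2 fold change -0.65 ± 0.10, adjusted p = 0.000102). SSX2 rested on 1 library, with 2.46 CPM in vehicle replicate 1 and 11.4 CPM in replicate 2, and its call was lost without the latter (adjusted p = 0.527) and on rescaling to a common total (0.0516). The call of GOLGA8R, which has close copies, was lost without vehicle replicate 1 (adjusted p = 0.102) or Dic replicate 1 (0.0984), and that of PTN without vehicle replicate 1 (0.0624), vehicle replicate 2 (0.088) or Dic replicate 1 (0.227).

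Each fit without 1 library sets 1 library against 2, so its spread comes from the other group alone. Calls held, lost or gained in such fits show only how far they depend on single libraries. Leaving out Dic replicate 1 left 509 called genes and leaving out Dic replicate 2 left 742, against 1814 without vehicle replicate 1 and 989 without vehicle replicate 2. A fit without the variance trend called 74 genes and a fit without the filter on low values 574. Rescaling each library to a common total called 1134 genes up and 231 down.

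The list with the largest median was that of ATF4 and the amino acid stress response. Of 22 genes tested 19 rose and none fell (21 and none adjusted over the list alone), with a median log2 fold change of 0.47 (camera adjusted p = 2.15e-29; adjusted p = 0.201 with an estimated correlation). CHAC1, which degrades glutathione, rose from 3.18 ± 0.0548 to 7.96 ± 1.42 CPM, the cystine transporter gene SLC7A11 from 56.3 ± 2.86 to 109 ± 3.71 CPM, and the pseudokinase gene TRIB3 from 129.9 ± 3.81 to 227 ± 14.4 CPM. Unfolded protein response genes of the endoplasmic reticulum moved in both directions. There 6 of 17 rose and 1 fell (7 and 4 adjusted over the list alone), with a median of -0.01 and a mean of 0.08, which differ in sign, and the list was not called (adjusted p = 0.143). Its risers included DNAJB9 (0.40), HERPUD1 (0.40), XBP1 (0.38) and EDEM1 (0.31). DNAJB9 lost its call without Dic replicate 1 (adjusted p = 0.114).

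Lipid synthesis genes rose as well. For cholesterol synthesis and uptake, 18 of 25 genes rose and none fell (18 and none adjusted over the list alone), with a median of 0.32 (camera adjusted p = 7.31e-22; adjusted p = 0.201 with an estimated correlation). Its risers included INSIG1 (log2 fold change 0.79 ± 0.05), MSMO1 (0.63) and STARD4 (0.58), and HMGCS1, an early enzyme of the pathway, rose from 271 ± 13.4 to 375 ± 8.47 CPM. For fatty acid synthesis 8 of 14 genes rose and none fell (10 and none adjusted over the list alone), with a median of 0.24 (camera adjusted p = 8.23e-11; adjusted p = 0.201 with an estimated correlation). SCD had the largest rise (1.18 ± 0.05), then the transcription factor gene SREBF1 (149 to 256 CPM), ACSL1 (92.8 to 155 CPM) and FASN (1044 to 1462 CPM).

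Of 29 lysosomal genes 11 rose and none fell (15 and none adjusted over the list alone), with a median of 0.15 (camera adjusted p = 7.06e-10; adjusted p = 0.201 with an estimated correlation). After GPNMB came NEU1 (70.9 ± 0.105 to 139 ± 2.59 CPM), the cholesterol-binding protein gene NPC2 (46.3 to 65.6 CPM) and SQSTM1, an autophagy receptor (163 to 226 CPM). Immediate early and ERK feedback genes rose in 9 of 23 cases and fell in 2 (14 and 2 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 3.39e-06; adjusted p = 0.201 with an estimated correlation). The risers with the largest change were DUSP4 (20.2 ± 2.11 to 39.2 ± 0.380 CPM), ETV5 (7.42 to 14.7 CPM), DUSP6 (6.37 to 10.6 CPM) and DUSP5 (4.13 to 6.74 CPM). DUSP5 lost its call without Dic replicate 1, where its log2 fold change was 0.526.

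Among stress lists with smaller medians, oxidative stress genes rose in 8 of 18 cases (10 up and 2 down adjusted over the list alone; median 0.20, adjusted p = 0.000391; adjusted p = 0.469 with an estimated correlation), among them GCLM, HMOX1, AKR1C1 and OSGIN1. Those 4 calls were each lost without Dic replicate 1 (adjusted p = 0.0578, 0.0817, 0.514 and 0.341), that of HMOX1 and AKR1C1 also without vehicle replicate 1 (0.0708 and 0.0595), and that of OSGIN1 without vehicle replicate 2 (0.0728). Hypoxia and glycolysis genes rose in 7 of 22 cases (10 adjusted over the list alone; median 0.12, adjusted p = 0.00116; adjusted p = 0.547 with an estimated correlation), including ALDOC (168 to 259 CPM) and VEGFA (458 to 634 CPM). That list was not called without vehicle replicate 2 (adjusted p = 0.0744). Genes of the p53 response rose in 6 of 21 cases (6 adjusted over the list alone; median 0.09, adjusted p = 0.0051; adjusted p = 0.404 with an estimated correlation), with GDF15 far ahead of the death receptor gene TNFRSF10B (93.8 to 125 CPM) and the cell cycle inhibitor gene CDKN1A (180 to 233 CPM).

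S-phase genes fell. Of 43 genes tested 22 fell and none rose (34 and none adjusted over the list alone), with a median of -0.22 (camera adjusted p = 6.52e-21; adjusted p = 0.404 with an estimated correlation). UHRF1 had the largest fall (-0.44 ± 0.06), and UNG, a uracil glycosylase, fell from 289 to 225 CPM, GINS2 from 71.6 to 57.3 CPM and MCM6 from 169 to 137 CPM. GINS2 and MCM6 lost their calls without Dic replicate 1 (adjusted p = 0.0573 and 0.061). Genes of G2 and mitosis moved little: 2 of 53 fell and 1 rose (the same counts adjusted over the list alone), with a median of -0.06 (adjusted p = 0.004; adjusted p = 0.671 with an estimated correlation). That list was not called without vehicle replicate 2 (adjusted p = 0.452) or Dic replicate 1 (0.23). MKI67 was at 300.1 ± 41.7 CPM with vehicle and 268 ± 9.51 CPM with Dic (adjusted p = 0.136). It passed with the replicate block (0.0116) and without vehicle replicate 2 (3.26e-06), where the spread is that of the Dic libraries alone. Tubulins and microtubule proteins fell in 6 of 21 cases (8 adjusted over the list alone; median -0.12, adjusted p = 0.00127; adjusted p = 0.331 with an estimated correlation). TUBB3 fell from 122 ± 3.99 to 99.6 ± 0.460 CPM (-0.29 ± 0.06, adjusted p = 0.00137). TUBB, TUBA1B and TUBG1 fell by 0.24, 0.24 and 0.23 on the log2 scale, and these 3 calls were lost without Dic replicate 1 (adjusted p = 0.164, 0.166 and 0.151), that of TUBA1B also without Dic replicate 2 (0.0954) and that of TUBG1 without vehicle replicate 2 (0.0707).

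Respiratory chain subunits fell in 3 of 30 cases, SDHA, ATP5G1 and CYC1 (the same count adjusted over the list alone; median -0.09, adjusted p = 3.92e-05; adjusted p = 0.525 with an estimated correlation); without vehicle replicate 2 the list was not called (adjusted p = 0.0503). CYC1 lost its call without vehicle replicate 2 (adjusted p = 0.0548), Dic replicate 1 (0.0638) or Dic replicate 2 (0.189), and ATP5G1 without Dic replicate 2 (0.0928). Of 30 ribosomal protein genes RPLP0 alone rose (none adjusted over the list alone; median 0.08, adjusted p = 0.00493; adjusted p = 0.66 with an estimated correlation), and the list was not called without vehicle replicate 1 (adjusted p = 0.148) or Dic replicate 1 (0.227), nor was RPLP0 without Dic replicate 1 (0.412) or Dic replicate 2 (0.299). No list passed at an adjusted p below 0.05 with an estimated correlation, and 7 of 26 did with fry: amino acid stress, cholesterol and fatty acid synthesis, lysosome, immediate early genes, unfolded protein response and growth factor receptors. Camera at the preset correlation called 13 of 26 lists.

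The 13 lists not called included several with named members that changed. Androgen response genes split, 5 up and 6 down of 25 (the same counts adjusted over the list alone; median -0.02, adjusted p = 0.211). The kallikrein genes KLK2 (69.4 ± 0.992 to 51.0 ± 0.348 CPM) and KLK3 (20.8 ± 0.128 to 16.1 ± 0.345 CPM, adjusted p = 0.0237) fell with SLC45A3, and TMPRSS2 (42.7 to 58.4 CPM) and ACPP (10.1 to 15.1 CPM) rose. KLK3 lost its call without vehicle replicate 2 (adjusted p = 0.0845), Dic replicate 1 (0.153) or Dic replicate 2 (0.0762) and on rescaling to a common total (0.0524), and ACPP without vehicle replicate 1 (0.0728) or Dic replicate 1 (0.0536). Drug transporters had 3 of 11 risers and no call as a list (4 up and 1 down adjusted over the list alone; adjusted p = 0.0654): ABCC2 (16.6 ± 2.05 to 28.0 ± 1.18 CPM), ABCC5 (53.3 to 73.7 CPM) and ABCC1 (58.7 to 72.4 CPM), the last without a call when vehicle replicate 2 (adjusted p = 0.0771) or Dic replicate 2 (0.0555) was left out. The list passed without vehicle replicate 1 (adjusted p = 0.0302).

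Growth factor receptors and ligands rose in 5 of 25 cases and fell in 1 (the same counts adjusted over the list alone; adjusted p = 0.211). MET, the HGF receptor, rose from 12.5 ± 0.409 to 18.4 ± 0.0454 CPM (0.53 ± 0.10, adjusted p = 0.00135), with AREG, HBEGF and VEGFA also up, whereas HGF was at 82.1 and 82.0 CPM with vehicle and 80.4 and 78.8 CPM with Dic (adjusted p = 0.736). HBEGF lost its call whichever library was left out (adjusted p from 0.0971 to 0.187) and AREG without Dic replicate 1 (0.0547). The remaining lists not called were mesenchymal genes (median 0.15; CD44 rose), replication-dependent histones (-0.22), heat shock (-0.02; HSPB1 and HSPE1 fell), interferon (0.04), cholinergic (0.03; CHRM4 rose), the BCL2 family (0.03; BMF and BCL2L2 rose), NF-kB targets (-0.02, with a mean of 0.04), epithelial genes (-0.002, with a mean of 0.02; PRSS8, CLDN3 and ESRP1 rose) and neuroendocrine genes (0.03; ENO2 rose). In fits of 1 library against 2, whose spread comes from the group of 2, the calls of CD44 and ESRP1 held without each library in turn, whereas those of HSPE1, CHRM4, BMF, BCL2L2, PRSS8, CLDN3 and ENO2 were lost without Dic replicate 1 (adjusted p = 0.179, 0.0704, 0.129, 0.179, 0.147, 0.151 and 0.301) and that of HSPB1 without Dic replicate 2 (0.429). On rescaling to a common total HSPB1 and HSPE1 also lost theirs (adjusted p = 0.056 and 0.0714). CHGA was at 0.417 CPM with vehicle and 0.199 CPM with Dic and was not tested. No member of the basal, endothelial, fibroblast and immune marker lists was called, each with fewer than 5 tested members.

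**Figure D2:**
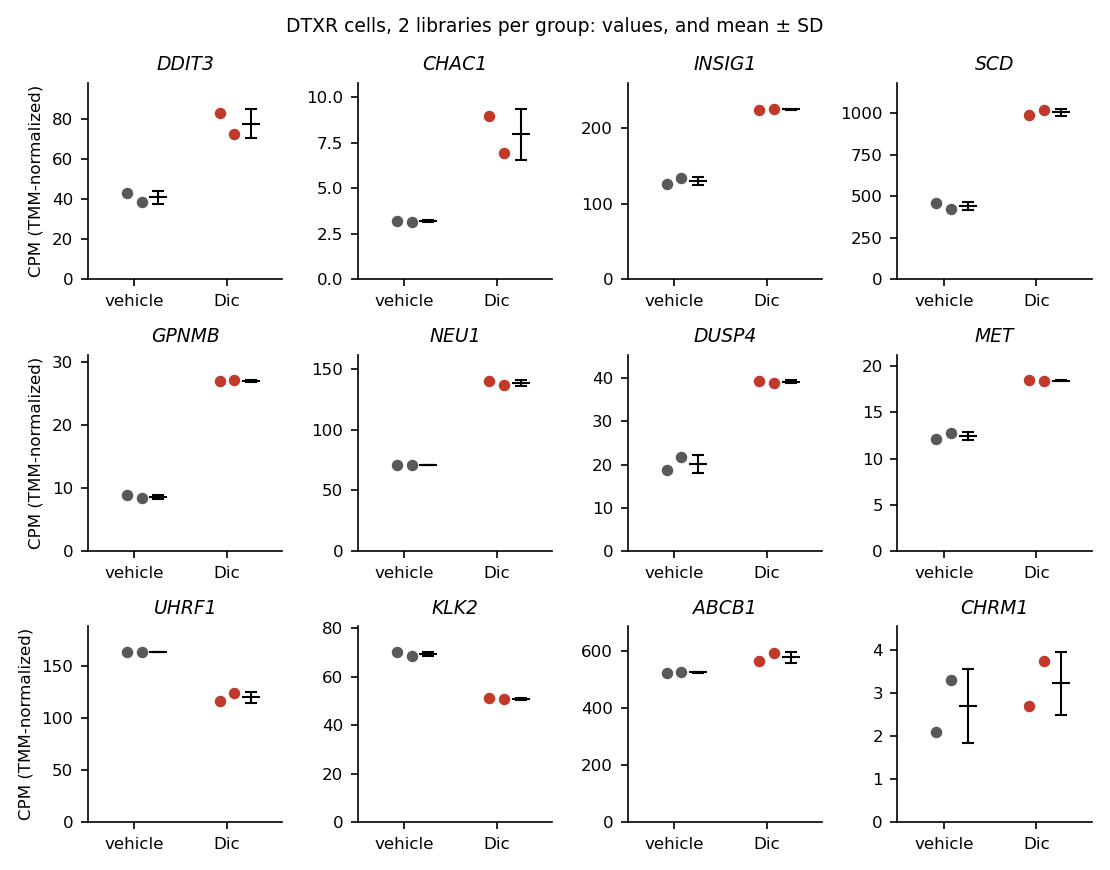
CPM of 12 genes in the 2 vehicle and 2 Dic libraries of DTXR cells, as points, with mean and SD beside them; each vertical axis starts at 0. DDIT3, CHAC1, INSIG1, SCD, GPNMB, NEU1, DUSP4 and MET were higher and UHRF1 and KLK2 lower in both Dic libraries. ABCB1 was also higher in both Dic libraries but was not called (limma adjusted p = 0.0672). The groups overlapped for CHRM1 (2.71 ± 0.852 and 3.23 ± 0.738 CPM).

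The last comparison asked whether Dic moved the genes that separate resistant from sensitive cells. Their source was 1 DTXR library, from which the vehicle-treated DTXR cells lay almost as far (SD of the log2 difference 0.85) as from DTXS (0.93), in tables normalized separately. The genes higher in DTXR did not fall as a set under Dic. Of 699 genes at least 2-fold higher in DTXR, Dic raised 114 and lowered 30. Calls covered 20.6% of them, against 9.3% of all 12833 genes measured in both tables. Fold changes were positive for 61.9% of them, against 51% of all genes. Their median log2 fold change was 0.08, against 0.00 for all genes. That median lay above all 10000 matched random lists, which ignore that genes can move together. Camera gave an adjusted p of 0.000293, or 0.463 with an estimated correlation, and fry gave a p of 0.0684. Genes higher in DTXR that Dic raised over vehicle included GPNMB, PDK4, CA12, GDF15, CREB3L1, TSC22D3, DUSP4 and ABCC2. Those that it lowered included KLK2, TUBB3 and STMN4. A rise over vehicle need not exceed the DTXR library. GPNMB was at 25.2 CPM in DTXS and 52.9 CPM in DTXR, but at 8.58 CPM with vehicle and 27.0 CPM with Dic. DUSP4 was at 24.6, 73.7, 20.2 and 39.2 CPM in that order, whereas GDF15 was at 39.4, 115.9, 123 and 287 CPM. KLK2 was 4.02-fold higher in DTXR (interval 3.45 to 4.71) and fell by 0.44 on the log2 scale under Dic. Of 429 genes at least 2-fold lower in DTXR, Dic raised 29 and lowered 19, with a median of 0.02 (camera adjusted p = 0.654). Calls covered 11.2% of them, near the 9.3% of all genes. FZD8, 59.3-fold lower in DTXR (48.3 to 73.6), was among those raised (0.82, adjusted p = 2.21e-07), as were SLC7A5 and PHGDH. Across the 12833 genes the log2 ratio of DTXR to DTXS and the log2 fold change under Dic had a Pearson correlation of 0.12 and a Spearman correlation of 0.17, a description across genes, which are not independent replicates. The set and the test shared no library.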

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

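The tests with DESeq2 and edgeR and the fit without rRNA and RNA polymerase III genes, which called 1276 genes, were chosen only after the result was seen; the other settings were set before the data were examined. Of the 1256 genes changed by Dic, 39 remained when a 2-fold change was also required and 640 at an adjusted p below 0.01, which follow from the thresholds. Without a filter on low values 574 genes changed, and without a variance trend 74; the cause was not tested. DESeq2 called 801 genes and edgeR 1181. Leaving out 1 library, with the spread then taken from the other group alone, gave 509 to 1814 genes. With the replicate number as a block 1998 genes changed, including all 1256; the replicates share only a number, and the correlation of their deviations was -0.0003. Camera called 13 lists at the preset correlation and 0 with an estimated correlation. Fry called 7, among them unfolded protein response and growth factor receptors, which are not among those 13. Leaving out 1 library also changed which lists camera called. For genes higher in DTXR the median under Dic was 0.079, with an adjusted p of 0.463 at the estimated correlation, and it ranged from 0.052 to 0.113 when 1 library was left out; for genes lower in DTXR it ranged from 0.002 to 0.035. The 1320 genes at least 2-fold apart between DTXR and DTXS became 630 with a pseudocount of 5 CPM and 841 with a mean of at least 5 CPM, since both discount low genes. Small fold changes changed sign: CHRM1 under Dic ranged from -0.038 to 0.435 when 1 library was left out, with -0.038 without vehicle replicate 1 (limma adjusted p = 0.941), and HGF was at 0.001 after rescaling to a common total (0.996).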

Other observations

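The genes in this paragraph, though not the lists, were chosen only after their values were seen, apart from ABCB1, CHRM3 and HGF. No tests were run on the differences described here. The DTXR library of the first table and the DTXR libraries with vehicle differed widely, although these tables were normalized separately and only values are given. Of 13461 genes, 2108 were at least 2-fold apart between the DTXR library and the vehicle mean, against 17 between the vehicle libraries. The albumin gene ALB had no read in DTXR and was at 173 and 176 CPM with vehicle, SPINK1 was at 0.241 against 69.5 and 64.2 CPM, and the chemokine gene CCL5 was at 71.8 CPM in DTXR and 0 in all vehicle and Dic libraries. HGF was at 4.64 CPM in DTXR and 82.1 and 82.0 CPM with vehicle, and CHRM3 at 41.3 against 2.30 and 2.11 CPM. DTXS lay near DTXR for these genes: ALB 0.0561, SPINK1 0.224, CCL5 65.6, HGF 1.74 and CHRM3 58.5 CPM. Their levels thus differed between the separately normalized sets of libraries, and not only among DTXR cells. The share of rRNA differed too, at 0.0% in DTXS and DTXR and 3.90% and 4.83% with vehicle. ABCB1 was alike in both (574 against 524 and 527 CPM). Of 22 hypoxia and glycolysis genes 16 were at least 2-fold higher with vehicle, with a median log2 difference of 1.59, and NDRG1 was at 15.8 CPM in DTXR against 296 and 269 CPM, NDUFA4L2 at 44.7 against 438 and 397 CPM and DDIT4 at 43.3 against 445 and 357 CPM.

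Of the tests below, those of RNA carry-over, rRNA synthesis, a swap and library scaling were chosen only after the result was seen. So was the look at the neighbours of UROD. Those of the neighbours of ABCB1 and of the second lysosomal list were written before they were run. They follow up patterns of the main comparisons and were not part of the design fixed beforehand.

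Ribosomal RNA and 3 of 5 RNA polymerase III transcripts were far lower in the Dic libraries. RN7SK, at 81.7 CPM with vehicle, fell by 3.80 on the log2 scale, but RN7SL1 and RN7SL2, also made by RNA polymerase III, rose by 0.36 and 0.30 on the log2 scale (limma adjusted p = 0.00139 and 0.00636). Less rRNA synthesis under Dic would not by itself account for the fall of those 3 transcripts, which the rRNA polymerase does not make. RMRP and RPPH1 were already among the largest falls when this was asked, so the outcome was largely known. A joint fall of both kinds of RNA in the cells stays open. Less carry-over of RNAs without a poly(A) tail could give the median of -3.30 over the 5 transcripts, but RN7SL1 and RN7SL2 went the other way. Replication-dependent histones, whose transcripts mostly lack such a tail, had a median of -0.22. Of their 10 tested members 0 were called (camera adjusted p = 0.19 for the list, at the preset correlation). Library handling coincided with treatment, so whether carry-over was the cause cannot be told. Among other non-coding RNAs, the small nucleolar RNA SNORD3A fell by 1.73, and NEAT1 and MALAT1 rose by 0.68 and 0.44.

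ABCB1 was 5115-fold higher in DTXR than in DTXS. A swap or wrong label is argued against by the vehicle libraries of DTXR cells, the lower of which had 524 CPM. A gain of the chromosome region could contribute: the 5 nearest measured genes on each side, with the paralog ABCB4 left out, had a median log2 ratio of 0.49, at the 98th percentile of 13192 windows of 10 genes, with 8 higher and RUNDC3B at 9.48 and 43.3 CPM. That median is far below the log2 ratio of 9.01 for ABCB1. A gain shared by these neighbours would thus not alone account for it. A median over neighbours cannot show a gain confined to ABCB1 and a few genes beside it. DNA copy number was not analysed here. The neighbours of UROD had a median of 0.74, at the 99.4th percentile, with HECTD3 at 81.0 and 441 CPM.

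The lysosomal, cholesterol and amino acid stress lists rose under Dic by camera at the preset correlation, but none passed with an estimated correlation (adjusted p = 0.201 for each). A second lysosomal list, with other genes, had a median of 0.14, and 14 of 37 genes rose and none fell, among them WIPI1 (6.74 to 12.1 CPM), FLCN (30.4 to 46.6 CPM) and RRAGD (83.3 to 120 CPM); its camera p was 1.65e-09 and, with an estimated correlation, 0.0493, unadjusted and no lower than those of the first lists (0.0387, 0.0243 and 0.0369, unadjusted, in the order above). This is consistent with a wider lysosomal response, a hypothesis that these data cannot tie to a mechanism. Library scaling as the whole cause is argued against, since the scalings tried moved the median of all genes by at most 0.042, less than the 0.145 of the lysosomal list. The replicates may be technical, in which case these p-values, including 0.0493, would be too small.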
